A study of Mus musculus with 4 samples.

How the data were processed

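RNA from sorted outer root sheath cells of 4 mice was hybridized to 4 Affymetrix mouse arrays, 1 per animal. The deposited values are log2 expression values of 45101 probe sets, made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA in general corrects for background, normalizes quantiles over a set of arrays and sums up the probes of a probe set. The software versions and the set of arrays that were normalized together are not given in the sources used here. Total RNA was extracted with a miRNeasy kit, and biotinylated cRNA was prepared by the standard protocol of the array maker, per the labels' protocols. The 2 male arrays share nearly the same quartiles, as do the 2 female arrays, but the quartiles differ between the sexes, so levels are set across the sexes only where that is said. Arrays have no count depth, and their number limits the precision.

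Groups follow the genotype in the labels. Mice with K14-rtTA and TRE-miR-125b formed the DTG group (n = 2), and mice with either part alone formed the control group (n = 2), each with 1 male and 1 female. DTG replicate 1 and control replicate 1 are the males, and DTG replicate 2 and control replicate 2 the females. The replicates are separate animals. Arrays of the same sex deviated together (Pearson r of 0.76 between the male to female differences of DTG and control), and the sex in the labels pairs them.

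The 64 Affymetrix control probe sets were left out of all tests. Of the rest, 34945 probe sets name 1 gene, 932 name several and 9160 are unnamed in the platform annotation used here; 34754 of those with 1 gene were matched to a current gene by gene ID, which changed 0 symbols. Probe sets were tested where their mean over the 4 arrays lay above the median of all means (5.54), which kept 22518. For gene lists, the brightest probe set that names 1 gene stood for each gene, and 11160 genes remained.

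DTG was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a trend) on the deposited log2 values, with genotype as the only term, Benjamini-Hochberg adjustment and a threshold of 0.05. Sex differences were tested with limma in a model with genotype and sex. The standard error from the model without sex is large (0.61 for each gene) because it takes in the sex difference. It was pooled over all probe sets, so p in that fit follows the size of the difference and not a probe set's own spread. The fit with sex as a block is given beside it. Within each sex, the log2 ratio of DTG to control was computed, and probe sets with at least a 1.5-fold difference the same way in both pairs were counted against the product of the pairs' counts over the number tested. Lists of genes were tested with camera in limma at a preset correlation of 0.01, two-sided, with adjustment over 22 lists, and the list median in each pair was ranked among 10000 random lists of equal size drawn from 20 bins of mean expression. The 22 tested lists cover published miR-125b targets, epithelial compartments of the skin, pathways, the immediate early response and other cell types, and a list of sex-linked genes checked the labels. Lists were written from general knowledge, and members below the filter or unmatched were not used.

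Genes were named by a rule fixed before the data were examined. It takes up to 12 genes per direction past the threshold with both DTG arrays beyond both control arrays, filled by the smallest unadjusted p among genes changed at least 1.5-fold in the same manner, up to 4 members of each list with the largest mean difference, and always Vdr, Prdm1, Bak1, Trp53, Lin28b and the sex-linked genes. Since no named gene passed the threshold, all 24 came from the fill. The ranking by the smaller pair ratio was chosen after the values were seen, as were Erbb3, Sgpl1, Krt34, Krt86 and the called unnamed probe set. Means ± SD are over the 2 pairs.

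The procedures were tested on simulated values for the same 22518 probe sets, with 50 changed by each of 1.5-fold, 2-fold, 4-fold and 8-fold. Without a term for sex, limma called 0% of them at any size. This 0% need not carry over to the real fit, which had a standard error of 0.61 for each gene and called a log2 difference of 3.78. With sex as a block, limma called 0%, 68%, 100% and 100%, along with 25 of 22318 unchanged probe sets. These shares need not carry over either. In the real limma fit with the block, the log2 difference of 3.78 had an adjusted p of 0.525, and Nrm, 3.41-fold lower, had 0.431. A count of 0 calls with the block therefore does not exclude large changes. The count past 1.5-fold in both pairs took in 16%, 88%, 100% and 100%, along with 92 unchanged probe sets, 46 each way. In a simulation over 11160 genes with the hair shaft list lowered 2-fold, camera called that list and 0 others. This step was revised after its first run, on the values that held the changed probe sets, had also called another list. Its noise was drawn independently for each gene, so it cannot show how camera fares with correlated list members.

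The alternatives were no filter, the brightest probe sets (mean above 7.83), limma with a trend or robust, sex as a block, quantile normalization of all 4 arrays, median centring, other correlations in camera, the mean of a gene's probe sets, a 2-fold limit, crossed pairing, and each array left out in turn. Loess correction and centring within pairs and combinations with the sex block were added after the data had been seen. A planned comparison of genes with and without miR-125b sites in their 3' untranslated regions was not run, since no transcript sequence was used here. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.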

Results

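Gene expression was measured in outer root sheath cells from the back skin of 4 FVB/N mice at postnatal day 4, with 1 Affymetrix mouse array per animal. The outer root sheath is the epithelial layer that encloses the growing hair. The 2 double transgenic mice (DTG, a male and a female) carried K14-rtTA, a doxycycline-dependent activator under the keratin 14 promoter of basal keratinocytes, together with TRE-miR-125b, which makes the microRNA miR-125b when that activator binds. The male control carried TRE-miR-125b without the activator, and the female control carried K14-rtTA without the microRNA gene. All 4 mice also carried K14-H2BGFP, a nuclear green label of keratin 14 cells, and all received doxycycline for 24 hours from day 3. Cells high for α6 integrin and GFP were sorted after cells stained for CD34, CD45, CD114 or DAPI had been excluded, per the protocol given for each sample. The description of the series gives another sort, by Sox9-EGFP and K14-RFP, which matches none of the 4 genotypes and was not used here. The comparison asked which transcripts change within a day of switching on miR-125b in these cells. The microRNA itself was not analysed here.

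The deposited values of 45101 probe sets were on a log2 scale, and the arrays fell into the male and the female pair. The median was 5.17 in the male DTG and 5.18 in the male control array, against 5.96 in the female DTG and 5.92 in the female control array. Across probe sets, Pearson's r was 0.994 within each pair and lay between 0.973 and 0.978 for arrays of different sex. Probe sets on one array are not independent replicates. The 2 DTG arrays share a genotype and differed by sex much as the controls did, with a median male minus female difference over the tested probe sets of -0.65 in DTG and -0.71 in control. Sex and any separate handling of the pairs cannot be told apart here, so DTG was set against the control of the same sex in each ratio below.

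**Figure D1:**
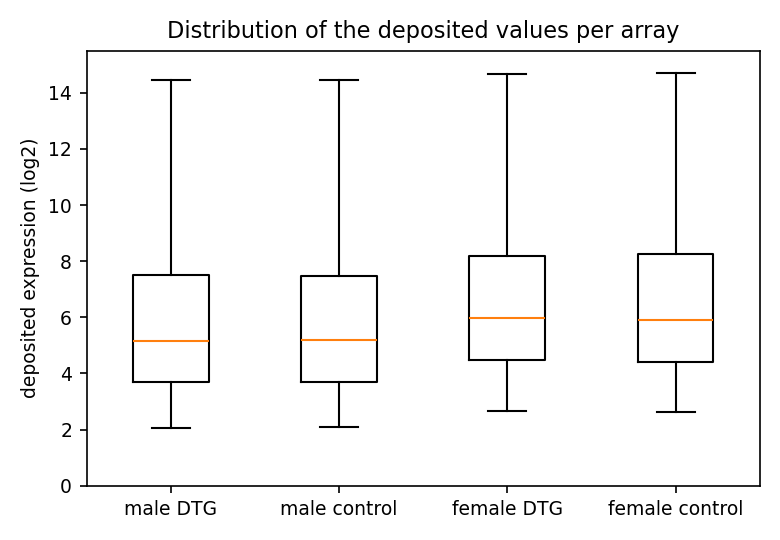
Deposited log2 expression on the 4 arrays, with the box from the lower to the upper quartile, the line at the median and the whiskers at the lowest and highest of 45101 probe sets. The medians of the male arrays (5.17 and 5.18) lie below those of the female arrays (5.96 and 5.92).

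In DTG cells, Nrm, which encodes the inner nuclear membrane protein nurim, was 3.41-fold lower than in controls, with a log2 ratio of -1.86 in the male and -1.68 in the female pair (mean -1.77 ± 0.13, SD, n = 2 pairs). Tmem123, a membrane receptor gene, was 2.56-fold lower (mean -1.36 ± 0.24, SD, n = 2 pairs). Mreg, the melanoregulin gene, was 2.39-fold lower (mean -1.26 ± 0.11) and Msrb3, which encodes a methionine sulfoxide reductase, was 2.30-fold lower (mean -1.20 ± 0.04). Fabp4, a fatty acid carrier, had ratios of -0.95 in the male and -1.45 in the female pair, Cd36, a fatty acid transporter, had -1.30 and -0.89, and Scarb1, the receptor for high-density lipoprotein, had -1.02 and -1.14. None of these genes passed the test over all probe sets described below.

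The other 5 genes at the lower end were Npl, Zbed4, Fam83h, Igfbp3 and Tgm2. Npl, an enzyme of sialic acid breakdown, had ratios of -2.25 in the male and -0.79 in the female pair. Zbed4, a zinc finger gene, had -1.05 and -1.43. Fam83h, whose product organises keratin filaments, had -1.26 and -1.05, but its second probe set gave only -0.45 and -0.27. Igfbp3, which encodes a binding protein of insulin-like growth factors, had -1.40 and -0.81, but its second probe set gave -1.39 and only -0.23. Tgm2, tissue transglutaminase, had -0.86 and -1.27, and all 5 of its probe sets above the filter were lower in both pairs.

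By the brightest probe set of each gene, the 12 genes at the higher end were at least 1.5-fold higher in 1 pair only. Padi4, a peptidylarginine deiminase gene, had a ratio of 0.51 in the male and 2.89 in the female pair, and Col6a3, a collagen VI chain gene, had 0.04 and 2.34. The reverse held for Magt1, a magnesium transporter gene, with 1.49 in the male and 0.23 in the female pair, and for Cpe, carboxypeptidase E, with 1.37 and 0.05. Gprasp2 (1.36 and 0.42), Get1 (1.30 and 0.23) and Sec23a (1.11 and 0.27) were also higher mainly in the male pair. Mmd had 1.22 and 0.49, but its other probe sets above the filter gave 1.02 and 0.64 and, the other way, -0.06 and 0.43. Clip3 had 1.12 and 0.43, and 0.38 and 0.56 by its second probe set. Zfp775 (0.91 and 0.48), Vegfb (0.80 and 0.52) and Reep1 (0.43 and 0.96) completed the 12. Ranked instead by the smaller of the pair ratios of each gene's brightest probe set, a rule chosen after the values were seen, Penk, the proenkephalin gene, led the genes that were higher, with 0.90 in the male and 0.76 in the female pair. Tox3 (0.87 and 0.74) and Bex1 (1.32 and 0.69) followed.

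With limma over 22518 probe sets and no term for sex, 1 probe set was higher in DTG and 0 were lower at an adjusted p under 0.05, and at an unadjusted p under 0.05 the counts were 3 and 9. The called probe set names no gene in the annotation used here. It measured 8.85 in the male DTG against 3.93 in the male control, and 9.58 in the female DTG against 6.93 in the female control, a mean log2 difference of 3.78 ± 0.61 (SE, limma, adjusted p = 1.67e-05). The male control value lay within the range of the probe sets of Xist, which males do not express, on the same array (2.55 to 4.48). It may lie near background, in which case the male ratio and the mean would be lower bounds. The standard error of 0.61 is pooled over all probe sets and leaves out this one's own spread (SD 1.61 over the 2 pairs). With sex as a block, its adjusted p in limma was 0.525 and 0 probe sets passed in either direction, with a smallest adjusted p of 0.431. At an unadjusted p under 0.05, 415 were higher and 1012 lower. With no change at all, a share of about 0.05 of the 22518 would fall under that limit, so these counts are not numbers of changed probe sets. A comparison of 2 against 2 arrays cannot reach p = 0.05 in an exact two-sided permutation test, whose smallest p is 0.333.

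Most of the probe sets that differed at least 1.5-fold the same way in both pairs were lower in DTG. In the male pair alone, 582 probe sets were at least 1.5-fold higher and 607 lower, and in the female pair 255 were higher and 937 lower. At least 1.5-fold lower in both pairs were 141 probe sets, which name 116 genes, and 11 probe sets were at least 1.5-fold higher in both. Besides the genes above, those lower in both included the inner root sheath keratin genes Krt28 (-0.84 and -0.88) and Krt71 (-0.67 and -0.69), the hair shaft gene Krtap8-1 (-0.81 and -1.02), the fatty acid desaturase gene Scd1 (-0.59 and -0.88), the cholesterol synthesis gene Dhcr7 (-0.88 and -0.85) and Lfng, which encodes a glycosyltransferase acting on Notch receptors (-0.91 and -0.68). At the stricter limit of 2-fold, 12 probe sets were lower and 1 was higher in both pairs.

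If the pairs were independent, 25.3 probe sets would be expected 1.5-fold lower in both and 6.59 higher in both. Probe sets that moved apart were also more than independence gives. The number 1.5-fold higher in the male and lower in the female pair was 61 against an expected 24.2, and the number lower in the male and higher in the female pair was 19 against 6.87. Across all 22518 probe sets, the ratios of the pairs were nearly unrelated, with a Pearson r of 0.08 and a Spearman rho of 0.05, where probe sets are not independent replicates. The same correlation was 0.76 between the male to female ratios of DTG and control, and -0.72 when each DTG array was set against the control of the other sex. The pairs share no array, so no chance correlation arises from a common control.

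**Figure D2:**
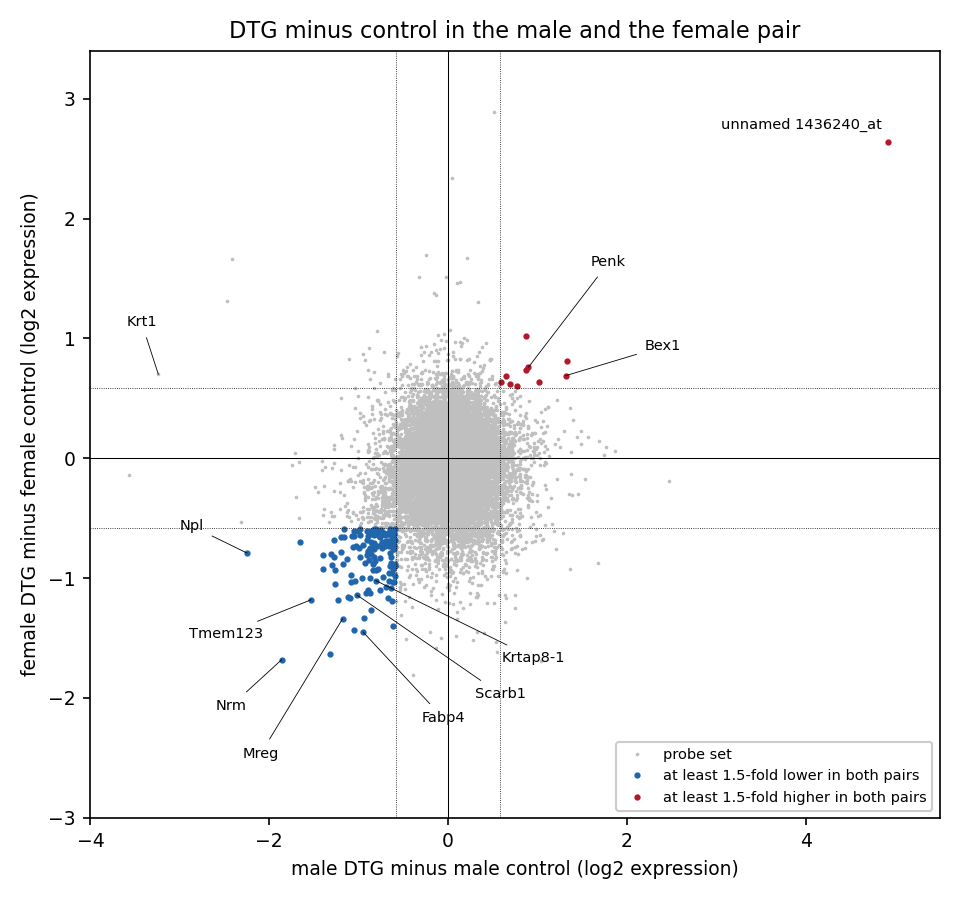
Log2 ratio of DTG to control in the male pair (horizontal axis) and in the female pair (vertical axis) for 22518 probe sets, 1 point each, with dotted lines at 1.5-fold. The 141 probe sets at least 1.5-fold lower in both pairs (blue) outnumber the 11 that were higher in both (red), and the unnamed probe set called by limma stands apart at 4.92 and 2.64.

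Genes published as targets of miR-125b were lower in DTG as a group with a preset correlation between genes, but not with an estimated one. The shift of the targets passed the camera test with the preset correlation of 0.01 (limma, adjusted p = 2.23e-05, and 4.05e-05 with sex as a block) and with a preset of 0.05 (adjusted p = 0.00416), but not with a correlation estimated from the 4 arrays (adjusted p = 0.872 with an estimated correlation). With 1 array left out, which leaves the sexes unequal between the groups, the targets stayed lower in each fit. At the preset correlation of 0.01, camera did not call them only without DTG replicate 1, the male. Of 29 measured targets, 16 were lower in both pairs and 1, Erbb2, was higher in both (0.26 and 0.31). By comparison, 25.1% of all 11160 genes were lower in both and 26.9% higher in both. The median ratio of the targets was -0.27 in the male and -0.15 in the female pair, which lay at percentiles 0 and 0.46 of 10000 random lists matched on expression. With sex as a block in limma, 6 targets fell when adjusted over the list alone and 0 over all probe sets. Without the block, 0 fell by either adjustment. These 6 were Trp53inp1, a p53-induced gene (-0.96 and -0.49), Edn1, endothelin 1 (-0.82 and -0.47), Bap1, a deubiquitinase gene (-0.62 and -0.56), Bmf, a pro-apoptotic gene of the Bcl-2 family (-0.42 and -0.69), Erbb3, a receptor kinase gene (-0.53 and -0.58), and Sgpl1, sphingosine phosphate lyase (-0.70 and -0.41). Their adjusted p over the list alone lay between 0.0426 and 0.0435. Vdr, the vitamin D receptor gene, had ratios of -0.58 and -0.30. Prdm1, a transcriptional repressor gene, had -0.32 and 0.45. Bak1, a pro-apoptotic gene, had -0.01 and -0.13. Lin28b was dim on all 4 arrays (2.60 to 3.02), and Trp53 was not analysed here.

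The medians of 2 lists of differentiated hair genes were lower in both pairs. Camera called both lists lower with the preset correlation but neither with an estimated one (adjusted p = 0.508 with an estimated correlation for both). It called both higher without DTG replicate 2 or without control replicate 1, with the values given below. These fits have no term for sex and leave relatively more males in DTG than in control. Both lists were far higher in males, with a median male minus female difference of 2.39 (hair shaft) and 1.83 (inner root sheath). The sex difference alone would turn the lists, so these fits cannot test the effect of genotype. Of 12 inner root sheath genes, 10 were lower and 0 higher in both pairs, with medians of -0.43 in the male and -0.70 in the female pair. When adjusted over the list alone in limma with sex as a block, 6 of them fell (0 without the block). Krt28 and Krt71 are given above, Krt25 had -0.48 and -0.84, and Tchh, the trichohyalin gene, had -0.29 and -0.92. Of 20 hair shaft genes, 13 were lower and 1 higher in both pairs, with medians of -0.81 and -0.18. When adjusted over the list alone with sex as a block, 10 fell (0 without it). Among them were the keratin-associated genes Krtap13-1 (-1.10 and -1.17), Krtap15 (-1.26 and -0.93), Krtap8-1 (-0.81 and -1.02) and Krtap11-1 (-0.84 and -0.93). Some hair keratins were lower almost only in the male pair, as with Krt34 (-1.41 and -0.10) and Krt86 (-1.38 and -0.07). Both were dim in the females, with means of 5.30 and 5.13 against 8.24 and 7.43 in the males. A fall in the female pair may be hard to see at such levels, but dimness does not always hide one. Among the probe sets lower in both pairs, Krtap7-1 measured 4.58 in the female DTG against 5.40 in the female control. Krt81 was also lower almost only in the male pair (-0.85 and -0.09), although it was brighter in the females (7.34 and 7.43). Over all probe sets, 0 members of either list passed.

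Other layers of the skin gave smaller or divided differences. Of 18 sebaceous gland genes, 8 were lower and 3 higher in both pairs, with medians of -0.02 and -0.16. When adjusted over the list alone with sex as a block in limma, 4 fell (0 without it), namely Far2, a fatty acyl reductase gene (-0.63 and -1.19), Pm20d1, an enzyme of N-acyl amino acids (-0.64 and -0.87), Scd1 (-0.59 and -0.88) and Elovl3, a fatty acid elongase gene (-0.55 and -0.60). Of 18 epidermal differentiation genes, 10 were lower and 2 higher in both pairs, with medians of -0.33 and -0.06, and 0 passed when adjusted over the list alone. The suprabasal keratins Krt1 (-3.24 and 0.70) and Krt10 (-1.71 and 0.04) were far lower in the male pair alone, whereas Sprr1a (-0.81 and -0.32) and the desmoglein gene Dsg1a (-0.44 and -0.40) were lower in both. Of 24 immediate early genes, which cell dissociation also induces, 11 were higher and 3 lower in both pairs, with medians of 0.10 and 0.12 and 0 passing over the list alone. Nr4a1 (0.36 and 0.71), Klf2 (0.32 and 0.51) and Fosb (0.36 and 0.46) were higher in both, and Atf3 was split (-0.16 and 0.95).

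With the preset correlation, camera called these 5 lists along with the targets. The adjusted p was 5.44e-11 for the inner root sheath, 1.45e-20 for the hair shaft, 0.00195 for the sebaceous gland and 1.34e-06 for epidermal differentiation, all lower, and 0.0128 for the immediate early genes, which were higher. None held with an estimated correlation, which gave adjusted p = 0.508 with an estimated correlation for the first 4 and adjusted p = 0.872 with an estimated correlation for the immediate early genes. The estimated correlation was 0.737 for the targets, 0.571 for the hair shaft, 0.407 for the inner root sheath and 0.884 for the immediate early genes. These estimates lie far above the presets of 0.01 and 0.05. The size of the correlation is still not the only source of this loss. With a preset correlation, camera takes its degrees of freedom from the genes, and with an estimated one from the arrays. The sebaceous list had an estimate of -0.00775, under the preset 0.01, yet was not called. Epidermal differentiation had an estimate of 0.043, while camera at a preset of 0.05 gave it an adjusted p of 0.000244. With so few arrays, the estimated version therefore cannot decide whether these lists shifted. The p-values at a preset correlation set genes against genes and do not measure the spread between the 4 animals. After all 4 arrays were quantile-normalized together, the targets kept an adjusted p of 8.08e-05 and the other 5 had 0.0915, 0.103, 0.173, 0.0648 and 0.0648 in the same order. Without DTG replicate 2 or without control replicate 1, which leaves the sexes unequal between the groups, the hair shaft (adjusted p = 5.9e-15 and 1.81e-31) and inner root sheath lists (5.43e-10 and 5.92e-11) were called higher instead, and so was epidermal differentiation without control replicate 1 (adjusted p = 0.000206). In the same fits, the sebaceous list (adjusted p = 0.354 and 0.921) and, without DTG replicate 2, epidermal differentiation (adjusted p = 0.945) were not called. The immediate early list was called without control replicate 1 (adjusted p = 0.0353) but not without DTG replicate 1 (adjusted p = 0.054), DTG replicate 2 (adjusted p = 0.362) or control replicate 2 (adjusted p = 0.203).

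**Figure D3:**
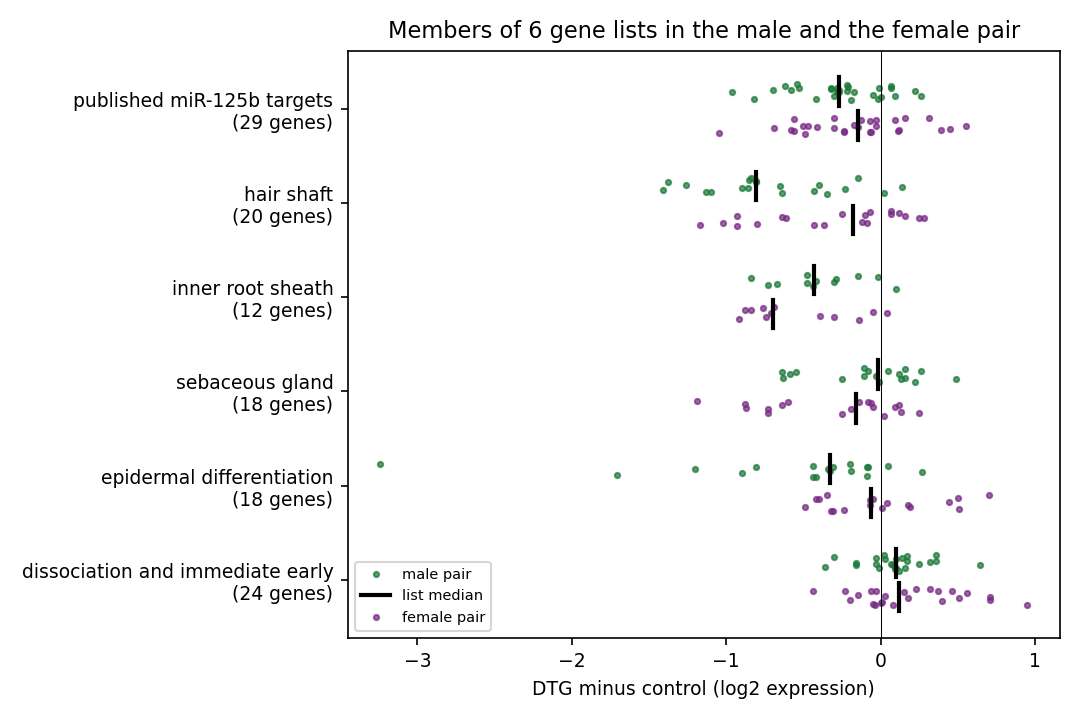
Log2 ratio of DTG to control for each measured member of 6 gene lists, 1 point per gene, in the male pair (green) and in the female pair (purple), with a bar at the list median. Medians of the targets (-0.27 and -0.15), hair shaft (-0.81 and -0.18) and inner root sheath (-0.43 and -0.70) lie below 0 in both pairs.

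Lists of the stem cell, basal and matrix compartments were not called with all 4 arrays and the settings used here first. Without a filter, the stem cell (adjusted p = 0.0456) and basal lists (0.0357) were called lower, as was the basal list by the mean of a gene's probe sets (0.046). With 1 array left out, the stem cell list was called lower without DTG replicate 1 (0.0138) and control replicate 2 (0.00328), and the basal list lower without control replicate 2 (0.01). The matrix list was called higher without control replicate 1 (0.0136) and lower without control replicate 2 (0.00328). Among 24 hair follicle stem cell and bulge genes (adjusted p = 0.161 in camera), Cd34 had ratios of -0.56 and -0.52, although cells stained for CD34 had been sorted out, Lgr6 had 0.45 and 0.39, Fst had -0.29 and -0.37, and Postn had -0.64 and -0.09. The 17 basal and outer root sheath keratinocyte genes (adjusted p = 0.0945) included Krt75 (-0.62 and -0.66), Krt6a (-0.74 and -0.32), Bcam (0.11 and 0.60) and Krt14 itself (-0.56 and -0.09). The 18 hair matrix progenitor genes (adjusted p = 0.506) included Ovol1 (0.18 and 1.0), Dlx3 (-0.38 and -0.39) and Ptch1 (-0.35 and -0.20). In all 3 lists, 0 members passed over the list alone, with sex as a block or without it.

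Pathway lists were not called either with those settings. Without a filter, cell cycle and cholesterol synthesis were called lower (adjusted p = 0.0357 for both). With 1 array left out, cholesterol synthesis was called lower without DTG replicate 1 (0.000143) and control replicate 2 (0.0345), and cell cycle lower without control replicate 1 (0.0221). Wnt signalling was called higher without control replicate 1 (0.00369) and lower without control replicate 2 (0.0248), and BMP and TGF-beta signalling higher without control replicate 1 (0.0168). Of 36 cell cycle genes, 16 were lower and 3 higher in both pairs. Adjusted p in camera was 0.214 for the cell cycle list, with Mcm3 at -0.37 and -0.35 and Rrm2 at -0.25 and -0.31, and 0.736 for 21 p53 response genes, with Pmaip1 at 0.31 and 0.57. It was 0.918 for Wnt signalling (22 genes, with Sfrp1 at -0.04 and -0.51), 0.389 for Hedgehog signalling (10 genes, with Gli3 at -0.44 and -0.05), and 0.545 for BMP and TGF-beta signalling (18 genes, with Id3 at 0.13 and 0.59). For 13 Notch signalling genes (adjusted p = 0.257), Lfng fell when adjusted over the list alone with sex as a block (limma, adjusted p = 0.0169), and 0 fell without it. Hes1, a Notch effector, had -0.40 and -0.47 and the feedback gene Nrarp had 0.80 and 0.25. For 17 cholesterol synthesis genes (adjusted p = 0.16), Dhcr7, which makes cholesterol in the last step of its pathway, fell with the block over the list alone (limma, adjusted p = 0.0106). Without the block, 0 of them fell. The interferon list kept 7 measured genes (adjusted p = 0.918), with Rsad2 at -0.33 and -0.11.

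Lists of other cell types were not called with those settings, but some were when 1 array was left out, which leaves the sexes unequal between the groups. The melanocyte and nerve sheath list was called lower without DTG replicate 1 (adjusted p = 9.15e-09) and control replicate 2 (9e-15) and higher without DTG replicate 2 (3.3e-06) and control replicate 1 (1.74e-13), turning in the same fits as the hair shaft list. The fibroblast and dermal papilla list turned alike, lower in the first 2 fits (0.00158 and 0.00579) and higher in the last 2 (5e-08 and 2.94e-08). The endothelial and mural list was called lower without a filter (0.00993), without DTG replicate 1 (0.00778) and without control replicate 2 (0.0248). With all arrays, the 14 fibroblast and dermal papilla genes (adjusted p = 0.223) included Lum (0.26 and 0.66), Pdgfrb (0.46 and 0.34) and Vim (0.31 and -0.86). The 7 endothelial and mural genes (adjusted p = 0.195) included Tagln (0.15 and -0.92) and Tek (-0.63 and -0.10). Only 3 immune genes were measured above the filter (adjusted p = 0.926), with Csf1r at -0.03 and -0.17. The 11 melanocyte and nerve sheath genes (adjusted p = 0.223) included Mlana (-0.69 and -0.12) and Slc45a2 (-0.55 and -0.29). Of 4 muscle, fat and red cell genes (adjusted p = 0.223), the fat cell gene Fabp4 fell when adjusted over the list alone with sex as a block (limma, adjusted p = 0.00151), and 0 fell without it.

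The arrays of the 2 sexes, which may also have been handled or normalized apart, differed more than those of the 2 genotypes. Xist, the RNA of the inactive X chromosome, measured 13.33 in the female DTG and 13.43 in the female control against 4.37 and 4.48 in the males, and the Y-linked Eif2s3y measured 9.61 and 9.40 in the males against 3.50 and 3.38 in the females. The Y-linked Kdm5d measured 8.21 and 7.75 in the males and 2.99 in both females, and Uty measured 7.11 and 6.45 against 3.18 and 3.20. These levels match the sex given for each array. Hair genes followed sex too. The hair shaft list had a median of 2.39 (log2, male minus female) and the inner root sheath list a median of 1.83, while the median of all tested probe sets was -0.69. Krtap8-1 had a mean of 11.38 in the males and 7.73 in the females, a difference of 3.64 ± 0.14 (SE, limma, adjusted p = 0.000405), Krt33a differed by 3.79 ± 0.13 (adjusted p = 0.000322) and Tchh by 3.45 ± 0.19 (adjusted p = 0.000827).

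With limma and a term for genotype, 16810 of 22518 probe sets differed by sex, 523 of them higher and 16287 lower in the males. After quantile normalization of all 4 arrays together, 4402 differed, 2252 higher and 2150 lower in the males, and the list medians became 3.08 for the hair shaft and 2.51 for the inner root sheath. Male and female controls also differed in control genotype. Any separate handling or normalization of the pairs goes with sex too, so these counts cannot be credited to sex alone.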

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

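The count among dim probe sets was chosen after the data were seen, and no test of a cause was run on the values of this part. Krt1, a keratin of the suprabasal epidermis, differed in direction between the pairs. It was 7.29 in the male DTG against 10.53 in the male control, and 8.70 in the female DTG against 8.0 in the female control, so the male ratio minus the female ratio was -3.94. The differentiation genes Calm4 (-1.20 and 0.50) and Krtdap (-0.90 and 0.51) also had opposite signs, and Krt10, the partner of Krt1, had -1.71 and 0.04. With 1 ratio per pair, these differences between the pairs were not tested. The pairs differ in control genotype as well as in sex, so the differences cannot be credited to either.

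Cholesterol synthesis genes also parted between the pairs, which differ in control genotype as well as in sex. Their median ratio was 0.23 in the male pair, at percentile 99.85 of matched random lists, and -0.28 in the female pair, at percentile 0.01, a difference of 0.51 that was not tested. Msmo1 (0.58 and -0.47) and Sqle (0.50 and -0.26) showed the split, while Dhcr7 (-0.88 and -0.85) and Hsd17b7 (-0.29 and -0.28) were lower in both pairs and Sc5d (0.44 and 0.23) was higher in both.

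Among 22519 dim probe sets that the tests left out, 5 were at least 1.5-fold higher in DTG in both pairs and 13 were lower. The 3 higher ones with a gene name were Hmga2, a chromatin gene of fetal growth (0.72 in the male and 1.08 in the female pair), Mc2r, the corticotropin receptor gene (1.02 and 0.62), and Fmo2, a monooxygenase gene (0.59 and 0.63). Hmga2 measured 4.17 and 5.85 in the DTG arrays against 3.44 and 4.77 in the controls by this probe set, and its 2 brighter probe sets had smaller ratios, 0.37 in both pairs for one and 0.30 and 0.38 for the other. In the male control, the dim probe sets of Hmga2 (3.44) and Mc2r (3.68) lay below the array's lower quartile (3.69). Their male ratios may therefore be lower bounds.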

How the results depend on the processing

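The settings that were chosen after the data had been seen are loess correction and centring within pairs, and the sex block combined with a trend, with quantile normalization or with an estimated correlation. All 24 genes named from the comparison of DTG with control kept their direction and stayed short of the threshold in all 301 values under other settings; their selection, with both DTG arrays beyond both controls, favours that. The single probe set called higher was lost (0 called) after quantile normalization, after median centring, with sex as a block (a replicate block on the sex-matched pairs), and with that block plus a trend or quantile normalization. Among the brightest probe sets 0 were called, where it was left out untested because its mean lay under the limit. At an unadjusted p under 0.05, limma gave 415 higher and 1012 lower with the block. It gave 404 and 1098 with a trend too, and 521 and 998 after quantile normalization. With no change at all, a share of about 0.05 of the probe sets would fall under that limit. The block takes out the sex difference but leaves 1 residual degree of freedom. Without the test, at least 1.5-fold in both pairs were 11 probe sets higher and 141 lower. Leaving out 1 array, with the lone array of a group assumed to vary like the other group, called 1 to 3 probe sets higher and 2 to 4 lower (3 and 2 without the male DTG or the female control, 2 and 4 without the female DTG, 1 and 3 without the male control).

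The correlation of the pairs, 0.08, was 0.01 without a filter and 0.15 among the brightest probe sets, and -0.72 with crossed pairing, which sets different sexes against each other. Counts of 141 lower and 11 higher became 73 and 4 among the brightest probe sets, where fewer were tested, 12 and 1 at 2-fold, and 34 lower with crossed pairing; they stayed within 1.5 times under the other settings. Probe sets differing by sex were 35660 without a filter, 8453 among the brightest and 4402 after quantile normalization. Of 6 gene lists called, 0 were called with an estimated correlation, with or without the sex block, 1 after quantile normalization and 11 without a filter; the sex block alone called the same 6. Leaving out 1 array, which unbalances the sexes, called 5 to 13 (13 without the female control, 11 without the male control, 9 and 5 without the male and the female DTG). The cause of these differences was not tested beyond the changes of construction named. The planned comparison of genes with miR-125b sites was not run. Signal over background limits Lin28b and, in females, Eif2s3y, Kdm5d and Uty, which measured below the lower quartile of their arrays. The same holds in the male control for the dim probe sets of Hmga2 and Mc2r given above. Background may also limit the called probe set in the male control. Its 3.93 there lay above the lower quartile (3.69) but within the range of the Xist probe sets (2.55 to 4.48).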

Other observations

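The tests here of male against female gene lists, loess correction, swapped labels, published targets as the source of lower genes, keratin members, spike-in probe sets and distributions were chosen after the data were seen. Some melanocyte and fibroblast genes were higher in the male than in the female cells, with no test of the lists as wholes, in a comparison where any handling shared by the arrays of 1 sex goes with sex. Wif1, a secreted Wnt inhibitor, was 3.49 ± 0.16 higher in the males (log2, SE, limma, adjusted p = 0.000583) and 4.22 ± 0.17 higher after quantile normalization of all 4 arrays (adjusted p = 1.52e-05). Of 11 melanocyte and nerve sheath genes, 10 were higher in the males after quantile normalization (limma, adjusted p under 0.05; list median 1.67) and 0 lower, and as deposited 6 were higher and 1 lower (median 0.99). Of 14 fibroblast and dermal papilla genes, 10 were higher and 1 lower after quantile normalization (median 0.87), and 7 higher and 3 lower as deposited (median 0.22). Col3a1, a collagen gene, differed by 1.62 ± 0.13 as deposited (adjusted p = 0.00146). Dcn, another fibroblast gene, went the other way, with -1.28 ± 0.21 (adjusted p = 0.00268).

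Far more probe sets were at least 1.5-fold lower (141) than higher (11) in both pairs. A leftover offset or intensity trend within pairs is argued against as the whole source, since a loess correction of each pair left 142 lower and 10 higher. With 2 pairs, labels can be set in 2 ways, too few for a share under 0.05; the real labels put 152 probe sets past 1.5-fold the same way in both pairs, swapping 1 pair put 80 there, and 1 of the 2 ways reached 152. Repression by miR-125b is a candidate explanation, since the median of its published targets was low in both pairs. It lay at or below percentile 0.46 of matched random lists, but such lists ignore correlation between genes. With 1 array left out, which leaves the sexes unequal, camera did not call the targets only without the male DTG. With an estimated correlation it did not call them either (adjusted p = 0.872). That version estimated a correlation of 0.737 for the targets, far above the presets of 0.01 and 0.05. It rests on 4 arrays and called 0 lists, even the sebaceous one with an estimate of -0.00775, so it cannot decide. None of the 29 targets is itself 1.5-fold lower in both pairs and the genes that are were not searched for binding sites, so that explanation stays a hypothesis, beside other differences between these 4 animals.

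Of 20 hair shaft and 12 inner root sheath genes, 13 and 10 were lower in DTG in both pairs, with 0 passing over all probe sets, and camera called neither list with an estimated correlation (adjusted p = 0.508 for both) or after quantile normalization (0.103 and 0.0915). A smaller share of such cells in the DTG sorts may account for lower values and would lower their abundant transcripts together, although the sort, for cells high for α6 integrin and GFP, selects against them. Of 11 bright keratin and keratin-associated genes, 10 were lower in both pairs and Krt32 had -0.15 and 0.28; the mean over all 11 was -0.61 (SD 0.25) in the male and -0.60 (SD 0.40) in the female pair. The standard deviation of their mean ratios was 0.29 against 0.22 for 6943 genes of like level, neither tighter nor more than 2 times wider, so a smaller share of cells and lower expression per cell cannot be told apart. Krtap8-1 differed more by sex (11.78 in the male and 8.24 in the female control) than by genotype, and an effect of miR-125b on hair differentiation stays untested.

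The male and female arrays lay at different levels. One common scale factor is argued against, because 45 spike-in control probe sets had a median male minus female difference of 0.37, the 18 added at hybridization ranging from -0.16 to 0.47 and the 27 added at labelling from -0.70 to 1.22, while the median of all probe sets was -0.70. A difference between distributions alone is argued against too, because 2441 probe sets still differed at least 1.5-fold the same way in DTG and control after quantile normalization (10868 before). Separate summaries of the probes for each sex could leave offsets shared by both ratios. The quartiles, alike within each sex but not between the sexes, go with RMA run on each pair apart. The set normalized together is not stated, so this stays open, as do the sex of the animals and the hair content of the sorts. The control probe sets were sorted into kinds by their names.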
